A study of Arabidopsis thaliana with 4 samples.

How the data were processed

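RNA levels were measured on 4 Affymetrix Arabidopsis arrays, 2 of wild-type Col-0 rosettes and 2 of rosettes labelled 35S:∆13RAP2.12. Per the labels' protocols, seeds were kept at 4 °C for 2 days before growth, rosettes were taken at 4 weeks, and total RNA was labelled with biotin. Groups and replicate numbers come from the sample titles. The labels number the replicates but do not say that they came from separate plants or pools, so p-values measure the spread between these samples, which could be technical. The series describes a larger number of arrays than the 4 used here, and the others were not analysed here.

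The deposited values are RMA expression values on the log2 scale, per the submitters' processing notes for RMA and per the range of the values for the scale. RMA corrects background, normalizes arrays by quantiles and summarises the probes of a probe set. The software, its version and the probe set definition are not given in the sources used here. The table held 27826 probe sets, each named by 1 locus, and no spiked control probe sets. All 4 columns of values were used, and 0 were left aside. Of the loci, 27241 matched the reference gene table of assembly TAIR10.1 and 585 did not. The table gave symbols and gene order only. No genome build is named for the array, so no coordinates are printed. No detection calls or raw intensities were used, so signal over background is unknown for single probe sets.

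No further normalization, filter or pseudocount was applied. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no covariates), with Benjamini-Hochberg adjustment over all probe sets. A probe set was called at an adjusted p below 0.05, and counts at least 2-fold also needed a log2 change of at least 1 in size. The residual degrees of freedom were 2 and the prior degrees of freedom 2.55. Errors beside fold changes are the moderated standard errors, intervals are 95% intervals, and errors beside levels are SDs over 2 arrays. All 603 called probe sets had groups whose arrays did not overlap, as had 48.6% of all probe sets, where chance gives 33.3% for 2 arrays against 2.

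Gene lists, the designs, the rule for named genes and the alternatives were fixed before the data were examined. The 30 lists came from knowledge of the field, were matched by locus and held 427 distinct genes, 17 of them in more than 1 list. Each list was tested with limma's camera (two-sided, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation, fry, and lists without the hypoxia-induced genes were alternatives. Named genes were the ERF-VII genes, the 10 largest changes in each direction among called probe sets with groups that did not overlap, and up to 4 called members of each list with the largest changes (10 for hypoxia-induced genes). Where no member of a list passed, the member with the smallest p was named. AOX1A, ADH1, PDC1, SUS4 and PGB1 were always named. Genes named outside this rule are said to be so.

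Further alternatives were the replicate number as a block, quantile normalization applied again, median centring, a filter at the 25th percentile of mean level, eBayes with an intensity trend or robust, array weights, each array left out in turn, and adjusted p thresholds of 0.01 and 0.10.

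The tests were tried on simulated data for this comparison, 10 simulations of 27826 genes in 2 against 2 arrays with 200 changed genes. They recovered 3.71% of genes with a log2 change of 1, 73.9% of those with 2 and 95.8% of those with 4, and 4.97% of calls were unchanged genes. Small changes were thus mostly missed in these simulations. Simulated variances did not follow the level, and fewer genes changed than were called in the data, so the rates may differ in the data. A planted list of 52 genes, 39 of them raised by 3, was called in 10 of 10 simulations with the preset correlation and in 0 with an estimated one. The 52 and 39 equal the counts found for the hypoxia-induced genes below. An average of 0.2 unchanged lists was called per simulation with the preset correlation. Simulated genes varied independently of each other, so these runs cannot tell how either setting behaves on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.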

Results

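Transcript levels were measured in whole rosettes of Arabidopsis thaliana at an age of 4 weeks. The wild type was the accession Columbia-0 (Col-0). The other arrays were labelled 35S:∆13RAP2.12, a name for a shortened form of RAP2.12 under the 35S promoter, a viral promoter active in most plant tissues. RAP2.12 is a transcription factor of group VII of the ethylene response factors (ERF-VII), whose amino terminus marks it for oxygen-dependent breakdown, so that removal of this terminus gives a form that lasts in air. The comparison asks how rosettes labelled as carrying this form differ from the wild type in transcript levels. Plants grew in 12 h of light at 22 °C and a night temperature of 18 °C, and rosettes were taken 10 h after the start of the light period. There were 4 arrays, 2 for each line, and their number limits the precision of every value. Median log2 levels were 7.88 on both wild-type arrays, and 7.91 and 7.89 on the arrays labelled 35S:∆13RAP2.12. Pearson's r over probe sets, which are not independent replicates, was 0.993 within each group and 0.978 to 0.980 between arrays of different groups.

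RAP2.12 transcript was not measurably higher in the arrays labelled 35S:∆13RAP2.12. Its log2 level was 11.07 and 11.16 on the wild-type arrays, 11.11 ± 0.06 (SD, n = 2). It was 11.28 and 11.06 on the arrays labelled 35S:∆13RAP2.12, 11.17 ± 0.16 (SD, n = 2). The log2 difference was 0.06 (SE 0.13, 95% interval -0.30 to 0.41, limma adjusted p = 0.879). The level of RAP2.12 thus did not bear out the label, and every direction below is that of the arrays labelled 35S:∆13RAP2.12 against the wild type. Which part of the transcript the probe set reads is not given in the sources used here, so this level does not refute the label either. Of the other ERF-VII genes, HRE2, itself a hypoxia-induced member of the group, rose from 5.05 ± 0.48 to 8.92 ± 0.22 (log2 change 3.87, SE 0.27, adjusted p = 0.00996), which is 14.6-fold. RAP2.2 differed by 0.12 (adjusted p = 0.747), RAP2.3 by 0.47 (adjusted p = 0.288) and HRE1 by -0.10 (adjusted p = 0.867). HRE1 lay below the lower quartile of all probe sets in the wild type, at 3.94. Of the 5 ERF-VII genes, 1 was higher and 4 did not pass, and the count adjusted over the list alone was also 1.

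Increases in the arrays labelled 35S:∆13RAP2.12 were large, and the 10 largest ranged from 6.46 to 7.73 on the log2 scale. Of these 10 genes, 2 were on the list of hypoxia-induced genes: CML38, a calmodulin-like calcium sensor, at 7.02 (SE 0.33, adjusted p = 0.00482), and AT5G10040 at 7.20 (SE 0.16, adjusted p = 0.00173). CYP76C5, a cytochrome P450, rose from 2.22 ± 0.45 to 9.95 ± 0.20 (log2 change 7.73, SE 0.25, adjusted p = 0.00277). AT4G26460 rose by 7.73, HR4, a homologue of the RPW8 resistance proteins, by 7.68, and SRO4 by 6.91. LCR67, of the defensin-like family, rose by 6.82, the thioredoxin TH8 by 6.76, AT3G20395 by 6.74 and the noncoding RNA AT1G67105 by 6.46. In 7 of these 10 genes, CYP76C5, AT4G26460, HR4, AT5G10040, CML38, SRO4 and LCR67, the wild-type mean lay between 2.22 and 4.13, below the lower quartile of 4.82. Whether this signal was above background is unknown, so the exact sizes and order of these increases are not determined.

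The decreases were fewer and smaller. AT3G01345 fell from 11.10 ± 0.30 to 5.29 ± 0.31 (log2 change -5.80, SE 0.23, adjusted p = 0.00349). The noncoding RNA AT2G01422 changed by -5.24 and AT3G28320 by -4.32, followed by AT1G74130 at -3.48 and AT1G80555 at -3.30. MAF3, a MADS-box gene of the FLC family of flowering repressors, changed by -3.07 (SE 0.14, adjusted p = 0.00439). The remaining 4 of the 10 largest decreases were AT1G31690 at -2.51, AT1G77960 at -2.47, G6PD4, a glucose-6-phosphate dehydrogenase, at -2.24, and AT3G28310 at -2.23. All of these passed the threshold, with adjusted p from 0.00349 to 0.0460. In the arrays labelled 35S:∆13RAP2.12, AT1G74130 at 3.67 and AT1G77960 at 4.06 lay below the lower quartile of all probe sets, so the exact sizes of these 2 decreases are not determined.

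Over all 27826 probe sets, 603 differed between the groups at an adjusted p below 0.05 (limma, Benjamini-Hochberg). Of these, 485 were higher and 118 lower in the arrays labelled 35S:∆13RAP2.12, so that 80.4% were higher. At least 2-fold changes were found for 561 of them, 464 higher and 97 lower. The median size was 2.00 for the higher and 1.29 for the lower ones, in log2 units. In 150 of the higher probe sets the wild-type mean lay below the lower quartile of all probe sets, where a fold change depends on a signal near the low end of the scale. Among the genes described below, these included PDC1, AT2G17850, AT4G10265, FMO1, ACS2, KIN1 and SAG13. At an unadjusted p below 0.05 the directions were nearly even, 2185 higher and 2332 lower. When the prior variance followed the level, 1759 probe sets passed, 1040 higher and 719 lower. The count fell to 0 without wild type replicate 1, 29 without wild type replicate 2, 262 without replicate 1 and 315 without replicate 2 of the arrays labelled 35S:∆13RAP2.12, and the same 4 counts held for changes of at least 2-fold.

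**Figure D1:**
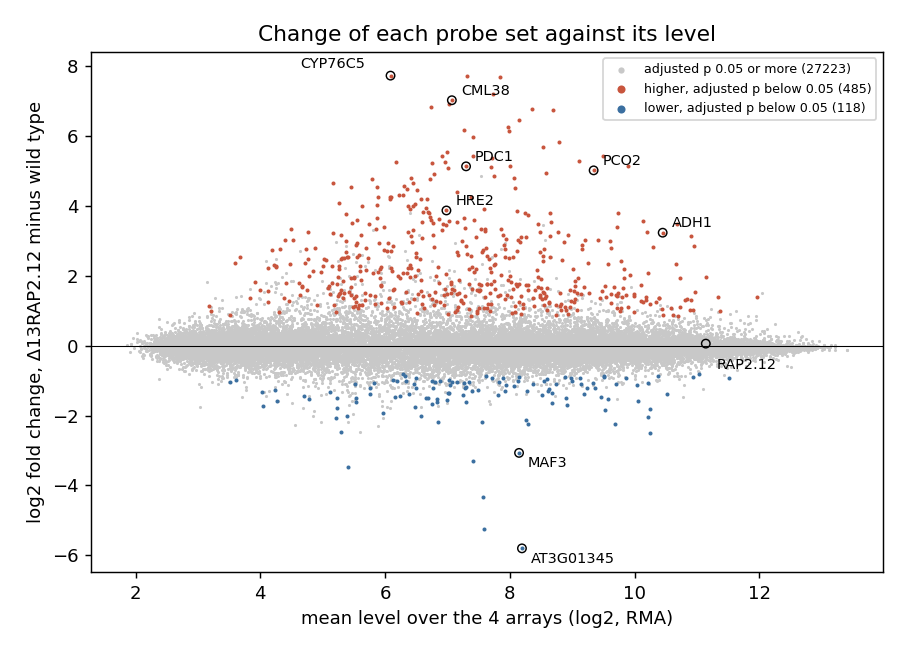
Log2 change of each of 27826 probe sets (arrays labelled 35S:∆13RAP2.12 minus wild type, 2 arrays each, y axis) against its mean log2 level over the 4 arrays (x axis), with 485 higher probe sets in red, 118 lower ones in blue and the rest in grey. RAP2.12 lies near 0 at 0.06, whereas CML38 and PDC1 lie at 7.02 and 5.13.

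Hypoxia genes rose as a group. Of 52 genes on the list of hypoxia-induced genes, 39 were higher, 0 lower and 13 did not pass. The median log2 change was 2.98, with quartiles of 1.33 and 3.80, and 49 of 52 had a positive change. PDC1, a pyruvate decarboxylase of ethanol fermentation, rose from 4.73 ± 0.19 to 9.86 ± 0.07 (log2 change 5.13, SE 0.14, adjusted p = 0.00277), with a wild-type level below the lower quartile of all probe sets. ADH1, the alcohol dehydrogenase of the same pathway, rose from 8.83 ± 0.61 to 12.07 ± 0.0014 (log2 change 3.23, SE 0.30, adjusted p = 0.0209), which is 9.40-fold. Further increases were 5.13 for SAD6, an acyl-carrier-protein desaturase, 5.02 for PCO2, a plant cysteine oxidase that acts in oxygen sensing, 3.57 for the phytoglobin PGB1 and 3.18 for the sucrose synthase SUS4. Genes known here by locus alone were AT4G39675 at 6.27, AT2G17850 at 6.17, AT1G33055 at 5.69, AT4G10265 at 5.44 and AT4G24110 at 5.14.

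Adjusted over the list alone, 49 of these genes were higher and 1 was lower. The list stood above the other genes in limma's camera test with a preset correlation of 0.01 (adjusted p = 1.13e-53). Camera with an estimated correlation did not call it (adjusted p = 0.132). That estimate was 0.0125, close to the preset value, so a high correlation between its genes does not account for the loss. The test with an estimated correlation has little power with 2 residual degrees of freedom. The list was not chosen on these samples. The number of higher members was 0 without wild type replicate 1, 10 without wild type replicate 2, and 28 and 29 without replicate 1 and replicate 2 of the arrays labelled 35S:∆13RAP2.12. The median stayed between 2.86 and 3.06 in these fits.

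**Figure D2:**
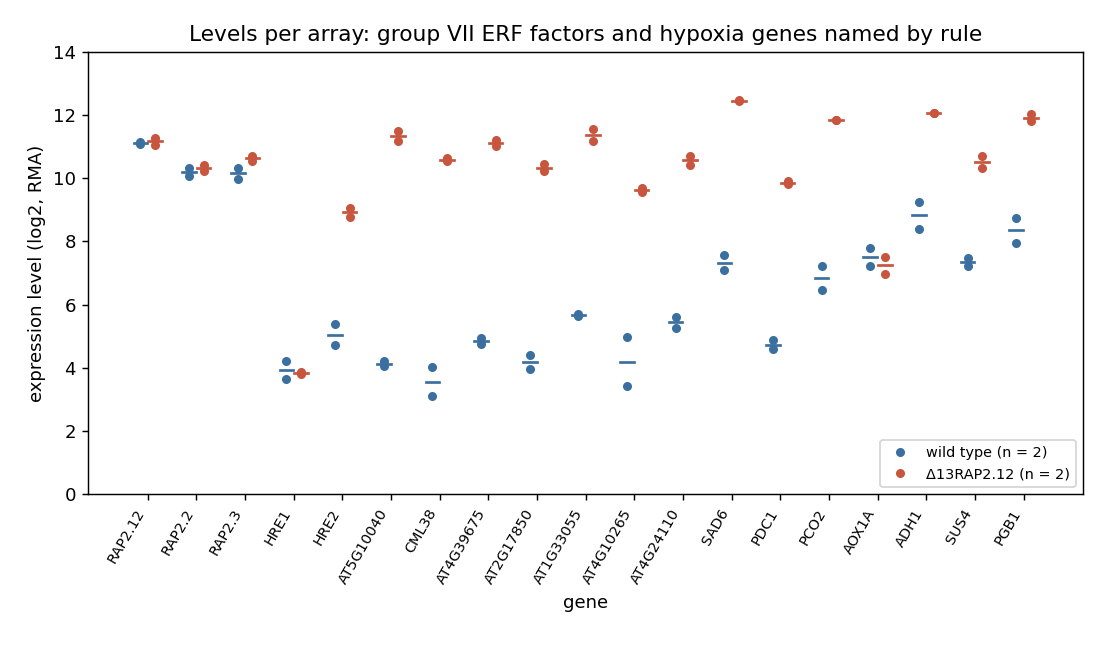
Log2 level per array (y axis, points, n = 2 per group; bars are group means) of the group VII ERF factors and the hypoxia genes named by rule, with wild type in blue and the arrays labelled 35S:∆13RAP2.12 in red. RAP2.12 overlaps between the groups at 11.11 and 11.17, while PDC1 moves from 4.73 to 9.86 and AOX1A overlaps.

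Transcripts of carbon metabolism changed at a few steps. In the list of fermentation and alanine metabolism, 3 of 13 genes were higher and 0 lower (6 and 0 adjusted over the list alone): PDC1, ADH1 and the alanine aminotransferase ALAAT1, which rose by 1.01 (SE 0.12, adjusted p = 0.0361). The list shifted upwards (median 0.51, camera adjusted p = 1.70e-06; adjusted p = 0.324 with an estimated correlation). Of 8 genes for sucrose breakdown, 2 were higher, the sucrose synthases SUS4 at 3.18 and SUS1 at 3.03, and none lower, with the same counts adjusted over the list alone. This list also shifted upwards (median 0.13, adjusted p = 0.00489; adjusted p = 0.324 with an estimated correlation), but not without its 2 hypoxia genes (adjusted p = 0.346). The size of its median depended on the arrays: it was 0.23 without wild type replicate 1, 0.36 without wild type replicate 2, and 0.060 and 0.27 without replicate 1 and replicate 2 of the arrays labelled 35S:∆13RAP2.12. No gene of cytosolic glycolysis passed among 22, where AT2G36580 had the smallest p at 0.65 (adjusted p = 0.0944). Its median of -0.07 and its mean of 0.06 differed in sign, and the list did not shift (adjusted p = 0.477). Among 14 genes of the TCA cycle none passed, with CSY4 at -0.33 (adjusted p = 0.297), and the list had a median of -0.13 (adjusted p = 0.164). Among 25 genes of starch synthesis and breakdown none passed either, with GBSS1 at 1.01 (adjusted p = 0.181) and a list median of -0.10 (adjusted p = 0.347). With each array left out in turn, the starch median ranged from -0.15 to -0.040. For each of these 3 lists the counts adjusted over the list alone were 0.

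Genes of oxygen sensing were higher in part. The list of the oxygen-dependent N-degron pathway holds enzymes that act in the breakdown of ERF-VII proteins, and also the acyl-CoA-binding proteins ACBP1 and ACBP2. In it, 2 of 10 genes were higher, the cysteine oxidases PCO2 at 5.02 and PCO1 at 3.24. The other 8 did not pass (3 higher and 0 lower adjusted over the list alone). The list missed the threshold (median 0.03, adjusted p = 0.0662) and passed with the low-signal filter (adjusted p = 0.0477). The sign of its median depended on the arrays. It was 0.12 without wild type replicate 1 and -0.061 without wild type replicate 2. Without replicate 1 and replicate 2 of the arrays labelled 35S:∆13RAP2.12 it was -0.0081 and 0.067. Without its 2 hypoxia genes its median was -0.05 and it did not pass (adjusted p = 0.843). The ERF-VII list itself passed (median 0.12, adjusted p = 0.0365; adjusted p = 0.382 with an estimated correlation), on HRE2 alone among its members. It did not pass without its 2 hypoxia genes (adjusted p = 0.235), without wild type replicate 1 (median 0.24, adjusted p = 0.0910) or without replicate 1 of the arrays labelled 35S:∆13RAP2.12 (median 0.028, adjusted p = 0.138). Without replicate 2 of those arrays it passed with a median of 0.22.

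Nitrate, mitochondrial and heat shock genes rose in part. In the list of nitrate assimilation and phytoglobins, 2 of 8 genes were higher, PGB1 and the nitrate reductase NIA1, which rose by 2.83 (SE 0.14, adjusted p = 0.00497), and 0 were lower (5 higher and 1 lower adjusted over the list alone). Its median was 0.63 (camera adjusted p = 0.00135; adjusted p = 0.324 with an estimated correlation). Of 7 genes of the mitochondrial dysfunction response, OM66, an outer-membrane ATPase, rose by 2.96 (SE 0.18, adjusted p = 0.00660), as the only 1 that passed, also adjusted over the list alone. AOX1A, the alternative oxidase often used as a marker of this response, had a difference of -0.27 (adjusted p = 0.710). The list passed with a median of 0.26 (adjusted p = 0.0257; adjusted p = 0.417 with an estimated correlation). Without wild type replicate 2 the median was 0.50. The list did not pass without wild type replicate 1 (median 0.18, adjusted p = 0.147), without replicate 1 of the arrays labelled 35S:∆13RAP2.12 (median 0.32, adjusted p = 0.0927) or with the low-signal filter (adjusted p = 0.0718). Small heat shock proteins made up the 4 of 15 heat shock genes that were higher: HSP17.6II at 3.91, HSP23.6 at 3.58, HSP17.6B at 1.54 and HSP17.6C at 1.53. None was lower, but 6 were higher and 2 lower adjusted over the list alone. The 2 lower ones, named outside the rule, were another small heat shock gene, HSP18.2, at -0.81 and HSFA2 at -0.55. The list median was 0.29 (adjusted p = 0.00147; adjusted p = 0.538 with an estimated correlation). This median was 0.11 without replicate 1 and 0.45 without replicate 2 of the arrays labelled 35S:∆13RAP2.12. Among 10 antioxidant enzymes none passed (2 higher and 0 lower adjusted over the list alone). The superoxide dismutase CSD1 was nearest at 0.72 (adjusted p = 0.0668), and the list did not shift (median 0.06, adjusted p = 0.164).

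Defence and hormone genes were higher in several lists. Of 22 genes of salicylic acid defence, 5 were higher and 0 lower (13 and 1 adjusted over the list alone). AIG1 rose by 4.85 (SE 0.40, adjusted p = 0.0150), the monooxygenase FMO1 of systemic resistance by 3.48, PBS3, an enzyme of salicylic acid synthesis, by 1.57, and WRKY18 by 1.03. PR1, a marker of this pathway named after its values were seen, had a difference of 4.85 that did not pass (adjusted p = 0.181), with levels of PR1 that lay far apart on the wild-type arrays, at 3.22 and 7.00. The list median was 0.59 (camera adjusted p = 3.79e-08; adjusted p = 0.324 with an estimated correlation). Of 23 jasmonate genes, 3 were higher and 0 lower (11 and 0 adjusted over the list alone): the repressors JAZ1 at 1.69 and JAZ3 at 1.21, and the synthesis enzyme AOC3 at 1.32. This list had a median of 0.60 (adjusted p = 5.06e-09; adjusted p = 0.417 with an estimated correlation), which was 0.39 without replicate 1 of the arrays labelled 35S:∆13RAP2.12. In the ethylene list, 2 of 22 genes were higher and 0 lower (4 and 1 adjusted over the list alone), the receptor ETR2, 4.28-fold, and the synthesis enzyme ACS2 at a log2 change of 1.78 from a wild-type level below the lower quartile. The median was 0.18 (adjusted p = 0.0257; adjusted p = 0.565 with an estimated correlation), and the call was lost without its 2 hypoxia genes (adjusted p = 0.184), without wild type replicate 2 (median 0.049, adjusted p = 0.142) and with the low-signal filter (adjusted p = 0.128). Without replicate 2 of the arrays labelled 35S:∆13RAP2.12 the list passed with a median of 0.075.

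Stress and ageing lists showed the same direction. Of 23 genes of abscisic acid, cold and dehydration response, 3 were higher and 0 lower (8 and 0 adjusted over the list alone): KIN1 at 2.75, RD20 at 1.74 and the phosphatase HAI1 at 1.24. The list median was 0.41 (adjusted p = 1.70e-06; adjusted p = 0.324 with an estimated correlation). Touch and wound genes had the second-largest median of the 30 lists, 0.89 (adjusted p = 6.62e-07; adjusted p = 0.324 with an estimated correlation). In that list, 2 of 10 passed, WRKY40 at 2.71 and the xyloglucan endotransglucosylase TCH4 at 1.16, 0 were lower, and 8 were higher and 0 lower adjusted over the list alone. In leaf senescence, 3 of 11 genes were higher and 0 lower (4 and 0 adjusted over the list alone): SAG13 at 2.77, SAG21 at 1.66 and WRKY6 at 1.36. The list median was 0.43 (adjusted p = 1.53e-05; adjusted p = 0.324 with an estimated correlation). Of 11 genes of the sugar starvation response, 2 were higher and 0 lower (4 and 0 adjusted over the list alone), TPS9 at 1.21 and TPS10 at 1.07, both of the trehalose-phosphate synthase family. The median was 0.47 (adjusted p = 0.000112; adjusted p = 0.324 with an estimated correlation).

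Some iron genes and 1 phosphate gene were lower. Of 9 iron homeostasis genes, 3 were lower: BHLH101 at -1.37 (SE 0.15, adjusted p = 0.0325), BHLH38 at -1.20 and BHLH39 at -1.13, transcription factors known to rise under iron deficiency. FER1, which encodes the iron store ferritin, was higher by 1.23 (SE 0.15, adjusted p = 0.0429). Adjusted over the list alone, 6 were lower and 1 higher, and the list median was -0.60 (adjusted p = 0.00975; adjusted p = 0.324 with an estimated correlation). Of 8 phosphate starvation genes, MGD3, a galactolipid synthase, was lower at -1.55 (SE 0.15, adjusted p = 0.0235), as the only 1 that passed, with 2 lower and 0 higher adjusted over the list alone. The list median was -0.34 (adjusted p = 0.0163; adjusted p = 0.565 with an estimated correlation).

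In the list of flavonoid and anthocyanin synthesis none of 19 genes passed (1 higher and 1 lower adjusted over the list alone), and 4CL3 was nearest at -0.74 (adjusted p = 0.0707). The list median of 0.28 passed narrowly (adjusted p = 0.0430; adjusted p = 0.658 with an estimated correlation). The call was lost without wild type replicate 1 (median 0.29, adjusted p = 0.112), without wild type replicate 2 (median 0.29, adjusted p = 0.140), and without replicate 1 of the arrays labelled 35S:∆13RAP2.12 (median 0.043, adjusted p = 0.627), as well as with array weights (adjusted p = 0.0510). It was also lost when the hypoxia-induced genes were taken out of the other lists (adjusted p = 0.0523), although this list holds 0 of them. Of 10 cell wall loosening genes, the expansin EXPA10 at 1.39 and TCH4 were higher and 0 lower (3 higher and 3 lower adjusted over the list alone), with a list median of -0.40 (adjusted p = 0.668). That median ranged from -0.42 to -0.18 with each array left out in turn.

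Photosynthesis, clock, cell division and marker lists held no gene that passed. The photosynthesis list of 25 genes had a median of -0.10 (camera adjusted p = 0.226), and LHCB2.4 had the smallest p at 0.88 (adjusted p = 0.257). The circadian clock list of 15 genes had a median of 0.02 (adjusted p = 0.378), with PRR9 at 1.09 (adjusted p = 0.0648), the only 1 higher adjusted over the list alone. The cell division list of 11 genes had a median of 0.03 (adjusted p = 0.783), with PCNA1 at -0.43 (adjusted p = 0.195). Its median ranged from -0.11 to 0.17 with each array left out in turn, so its sign is not determined. Lists of markers of other organs did not pass either. The 9 root markers had a median of 0.01 (adjusted p = 0.416), with PYK10 at 0.72 (adjusted p = 0.102), and 1 was higher adjusted over the list alone. The median of the root markers ranged from 0.0082 to 0.16 with each array left out in turn. With the low-signal filter it was 0.605 and did not pass (adjusted p = 0.0718). The 12 flower and flowering markers had a median of -0.16 (adjusted p = 0.242), with AG at -1.10 (adjusted p = 0.0690), and 2 were lower adjusted over the list alone. With each array left out in turn, the median of these markers ranged from -0.32 to -0.080. The 6 seed storage markers had a median of 0.01 (adjusted p = 0.783), with SESA2 at -0.14 (adjusted p = 0.790). The 9 reference genes had a median of -0.06 (adjusted p = 0.477), with ACT2 at -0.24 (adjusted p = 0.428). In the lists for photosynthesis, cell division, seed storage and reference genes, 0 members passed adjusted over the list alone.

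**Figure D3:**
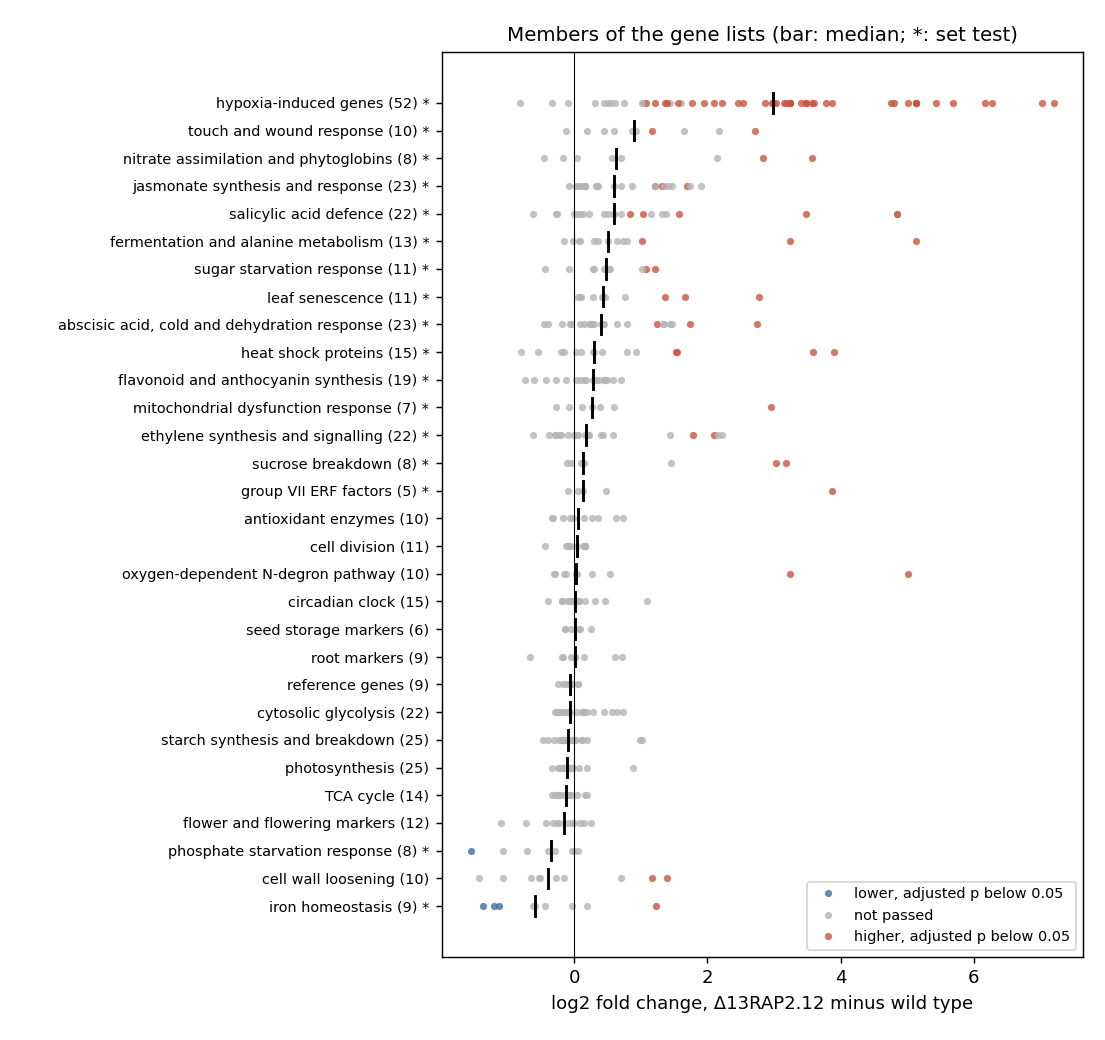
Log2 change of each member (points, x axis, arrays labelled 35S:∆13RAP2.12 minus wild type, 2 arrays each) of the 30 gene lists (y axis, number of genes in parentheses), with higher members in red, lower ones in blue and those that did not pass in grey. Bars are list medians and a star marks the 17 lists that passed the camera test with a preset correlation; hypoxia-induced genes stand furthest right with a median of 2.98, and iron homeostasis furthest left at -0.60.

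Over the 30 lists, 17 shifted in camera with a preset correlation, 15 upwards and 2 downwards. With a correlation estimated from the 4 arrays, 0 shifted, and the adjusted p of the 17 ranged from 0.132 to 0.658. This setting rests on 2 residual degrees of freedom, so its misses cannot decide whether a list shifted. Estimates lay near or under the preset 0.01 for hypoxia-induced genes (0.0125), leaf senescence (-0.090) and sucrose breakdown (-0.11). A high correlation thus does not account for the loss in these lists. In other lists that had shifted the estimate was higher, up to 0.57 for phosphate starvation. In simulated data of the same size, the estimated correlation found a planted list in 0 of 10 runs, and the preset correlation in 10 of 10. The simulated genes were independent, so these runs do not judge the preset correlation for lists of correlated genes. With fry, which tests whether a list's genes move one way on balance, 9 of the 17 passed. The 8 that did not were the lists for ERF-VII factors, mitochondrial dysfunction, heat shock, flavonoids, jasmonate, ethylene, sugar starvation and phosphate starvation, with adjusted p from 0.0568 to 0.481.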

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

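No direction of a called probe set could turn when an array was left out, since none of the 603 had overlapping groups. The number of calls depended on the variance model and the arrays. With the intensity trend it was 1759 (879 at least 2-fold, 681 higher and 198 lower), and 598 of the 603 were among them. At adjusted p thresholds of 0.01 and 0.10 it was 160 and 1203, and at 0.01 the higher hypoxia genes numbered 25. It was 648 after quantile normalization again (584 shared), 618 after median centring (594 shared), 902 with the low-signal filter (561 shared), 538 with robust eBayes (538 shared) and 578 with array weights (572 shared). With each array left out in turn it ranged from 0 to 315, also for changes of at least 2-fold, with 0 without wild type replicate 1, 29 without wild type replicate 2, and 262 and 315 without replicate 1 and replicate 2 of the arrays labelled 35S:∆13RAP2.12. These limma fits have 1 residual degree of freedom and assume that the lone array varies like the others. At an unadjusted p below 0.05, the fit without wild type replicate 1 still gave 4340 probe sets. Higher hypoxia genes ranged from 0 to 29, the hypoxia list's median from 2.86 to 3.06 and the lists that shifted from 14 to 17. Without wild type replicate 1, none of the 66 called named genes passed, and without wild type replicate 2, 14 did. With robust eBayes 5 of them did not pass (AT1G74130, WRKY18, TPS9, SAG21 and BHLH39), and with array weights 1 did not (SAG21).

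With an estimated correlation the lists that shifted fell from 17 to 0, and the hypoxia list's median of 2.98 had an adjusted p of 0.132. The simulated planted list, made of independent genes, was also missed at that setting. With fry, 9 lists passed. With the preset correlation and without the hypoxia-induced genes, 13 did. RAP2.12 ranged from -0.053 to 0.17 when an array was left out and passed in none of these fits. Also without a call, AOX1A ranged from -0.56 to 0.026, HRE1 from -0.38 to 0.18 and SESA2 from -0.35 to 0.074, and the cause was not tested.

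The replicate block gave 515 calls, of which 451 were shared, and 9 of the 66 named genes and the flavonoid and anthocyanin synthesis list (adjusted p = 0.0536) did not pass. Deviations of same-numbered arrays had a correlation of 0.0349 over probe sets, so the numbers were not taken as pairs. Averaging the probe sets of a gene was not run, since each locus has 1. Signal over background was not known, which limits levels near the low end.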

Other observations

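The family tests, the search for neighbouring calls, and the tests of an array swap, of probe reach, of a copy gain (both), of sequence variants as the cause of all calls, of low signal in either group and of the prior variance (both) were chosen after the results were seen, with the second copy gain test, this variant test (its bound of 50% lower set with the interval known) and the test of either group added once earlier tests of the same explanations had been seen, and the genes named here for themselves were chosen after their values were seen.

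Several gene families held more called members than chance gives for independent loci, among 223 families of at least 10 loci formed from shared symbol stems (one-sided Fisher's exact test, Benjamini-Hochberg over the families). Some called members have neighbouring locus numbers, such as BHLH38 and BHLH39, CRK6 and CRK7, or CML38 and AT1G76640. Neighbours were not thinned, shared probes were not checked, and the background was all 27241 loci, with or without a symbol. These p-values may therefore overstate the evidence. A shared stem need not mean related genes, as with SAG. Some called members, such as SAG13, BHLH38 and WRKY40, were already described above and are not separate evidence. Of 72 loci with WRKY symbols, transcription factors of defence and senescence, 8 were higher and 0 lower in the arrays labelled 35S:∆13RAP2.12 (adjusted p = 0.00631), with WRKY75 at 3.79 and WRKY46 at 1.99. Of 45 CRK loci, cysteine-rich receptor-like kinases, 6 were higher (adjusted p = 0.00761), such as CRK7 at 3.10, and CRK41 was lower at -1.11. Of 14 CML loci, calmodulin-like proteins, 4 were higher (adjusted p = 0.00631), including CML41 at 3.02 and CML37 at 2.29, and CML42 was lower at -1.17. Of 13 SAG loci, named for senescence, 4 were higher and 0 lower (adjusted p = 0.00631), among them BCB at 1.97. In the other direction, 4 of 22 loci with BHLH symbols were lower (adjusted p = 0.000480), the iron regulators BHLH38, BHLH39 and BHLH101 and the growth regulator PRE1 at -1.68, while 2 were higher. Of 80 SAUR loci, auxin-responsive genes whose close copies were not checked for shared probes, 4 were lower (adjusted p = 0.0429), with SAUR63 at -2.01, and 2 were higher.

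Other genes stood out on their own in the arrays labelled 35S:∆13RAP2.12. AOX1B, a second alternative oxidase, rose from 4.46 ± 0.47 to 9.56 ± 0.18 (SD, n = 2; log2 change 5.10, adjusted p = 0.00539), whereas AOX1A did not pass. The trehalose phosphatases TPPB and TPPD were higher by 2.77 and 2.57 and the trehalase TRE1 by 2.58, as single genes without a test of their pathway. QQS, a species-specific gene linked to starch content, rose by 5.43 (adjusted p = 0.0178). MAF4, a neighbour of MAF3, rose by 1.37 while MAF3 fell by 3.07, and MAF5 next to them did not pass at -0.42 (adjusted p = 0.805). LBD40 rose by 5.26 beside the noncoding RNA AT1G67105 at 6.46, and whether their probes read separate transcripts was not tested. The wild-type levels of AOX1B, QQS, LBD40, MAF4 and WRKY75, and of LBD26 and AT3G27990 named below, lay below the lower quartile of all probe sets, so the sizes of their changes are uncertain.

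RAP2.12 was not higher in the arrays labelled as its overexpressor. A swap of 1 array between the groups would leave arrays of different groups as similar as replicates, but the lowest r within a group exceeded the highest between groups by 0.0130. Saturation of the signal was argued against by the 7.20% of probe sets that had a higher mean level. A transgene transcript that the probes miss, or a low transgene level, stays open, since the upper 95% limit of the difference was 0.41 and probe sequences were not used here. An exchange of the labels of both groups would need the wild type to carry the hypoxia response, since 39 of 52 hypoxia genes were higher and 0 lower in the arrays labelled 35S:∆13RAP2.12, and a change in the native transcript stays open as untested.

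Called genes lay next to each other more often than chance gives: in the order of 27241 loci, 599 of them called, there were 55 neighbouring pairs of calls, 50 of them in 1 direction, against a median of 13 and a highest value of 27 in 10000 permutations (p = 1e-04, the smallest they can give). The densest stretch of 50 loci, on chromosome 3, held 12 calls (highest permuted 10, permutation p = 1e-04, the smallest possible), with 10 higher, such as LBD26 at 4.25, AT3G27990 at 5.26 and UMAMIT44 at 2.89, and 2 lower, AT3G28310 and AT3G28320. A second, separate stretch of 50 loci, on chromosome 1, held 10 calls, among them JAZ1 and FMO1. That equals the highest permuted count, and the 95th percentile of the permutations was 7. The second stretch was not examined further, so the density of calls was not particular to chromosome 3. Probe sets that read 1 transcript do not account for the stretch on chromosome 3. With only the first call of each run kept, the highest count was 10 (permutation p = 0.000500). Their part in the neighbouring pairs was not tested. The median change was 0.19 over all loci of the stretch on chromosome 3 (95% bootstrap interval 0.037 to 0.46). Over the 19 with a wild-type level above the median of all probe sets it was 0.051 (-0.32 to 0.38). Of these 19, 0 were higher calls, so a median below the size of the higher calls was largely set in advance. The stretch as a whole thus rose less than its higher calls, the smallest of which was 1.33. That size is above a log2 change of 1, a doubling, so a gained copy of smaller effect would also have stayed below it. These values therefore cannot decide on a gained copy, and a gain of the whole stretch or of part of it stays open. Sequence variants of another background, which lower a signal, do not account for all 12 calls, as 16.7% of them were lower (exact 95% interval 2.09% to 48.4%), but they stay open for the 2 lower ones, where 12 calls were too few for a comparison with the 114 lower of 587 outside (two-sided Fisher's exact p = 1) to exclude them, and no biological explanation was tested.

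More probe sets were called higher than lower, 485 against 118. The median of all log2 changes was -0.043. RMA had already drawn the arrays together by quantiles, which constrains this median, so it cannot decide on a normalization offset. After median centring 77.7% of calls were still higher, but that median moved only to -0.069, which tested little. Quantile normalization again left 75.9% of calls higher, but it moved that median only to -0.039 and so also tested little. A normalization offset thus stays open, whether of the same size for all probe sets or varying with the level. Low signal stays open too, since 78.1% of the 228 calls above the median level were higher but the increase itself lifted 85 of those 178 over it, and with both group means above it 72.1% of 129 calls were higher, with an interval too wide to decide (Wilson 95% interval 63.8% to 79.1%). With a prior variance that follows the level the share fell to 59.1% of 1759 calls, but among the 879 of at least 2-fold it stayed at 77.5%, 681 higher and 198 lower. Calls under 2-fold were 21 higher and 21 lower with 1 prior variance, and 359 higher and 521 lower when it followed the level, so the share over all calls depends on how many small changes pass, while 1 prior variance does not account for the imbalance among changes of at least 2-fold, for which the difference between the lines stays open as untested.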
